A study of Homo sapiens with 25 samples.

How the data were processed

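The series holds RNA sequencing of 25 libraries from A549 and NCI-H460, established lines of human non-small cell lung cancer. Per the labels, cells were transfected for 24 h with 25 nM of an antisense oligonucleotide (ASO), RNA was extracted with a column kit, and libraries were made with the NEBNext Ultra RNA kit. Per the labels, each line has 5 groups: a control ASO, 2 ASOs against candidate 42 (ASO3 and ASO5) and 2 ASOs against candidate 240 (ASO1 and ASO3). A549 has 3 libraries per group (replicates 3, 4 and 5) and NCI-H460 has 2 (replicates 1 and 2). The labels do not say whether libraries of a group come from separate cultures or transfections, so every p-value measures only the spread between these libraries. The ASO sequences were not used here.

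The tools named are kallisto and sleuth 0.30 with genome build hg38, per the submitters' processing notes. The annotation release and the handling of strand are not given in the sources used here. The main table was deposited as a signal per gene name, a TPM value (transcripts per 1e6) for each of 59427 gene names in each library. The column sums run from 924350 to 1179224 and not to a fixed total, so the TPM values deposited by the authors had been rescaled between libraries. TPM values keep no record of the number of reads, so the depth of each library is unknown, and no counting interval or detection limit is given. Values of very short genes named below, such as MIR641, MIR4442, MIR4502 and SNORA11 (67 to 128 bp), may rest on few reads. They are not taken as measures of the mature small RNAs.

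The authors also deposited 8 tables, each comparing an ASO with the control of its line. Per the file headers these hold a log2 fold change and a q-value per gene, with a mean signal for the ASO and the control libraries. How the authors adjusted the q-value is not given in the sources used here. The log2 values equal the ratio of the deposited means. The ASO means in the A549 tables equal the means of the TPM table (ratio 1), while the control means are scaled separately in each table, at ratios of 0.989 to 1 in A549. In the NCI-H460 tables the deposited means lie at 0.6667 of the means over the 2 ASO libraries and at 0.6354 to 0.6763 of the means over the 2 control libraries. In the TPM table the control columns therefore carry the scaling of the candidate 240 ASO1 comparison only. Values from these tables are always named as the authors' own.

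All fold changes and tests were computed from the TPM table with R 4.3.3 and limma 3.58.1. Values were taken as log2(TPM + 0.5), which understates fold changes of genes at low values. Genes with a mean of at least 1 TPM over a line's libraries were tested, 14740 in A549 and 13774 in NCI-H460. A linear model with a mean per group was fitted to all 5 groups of a line (lmFit, contrasts.fit, eBayes with a trend), which leaves 10 residual degrees of freedom in A549 and 5 in NCI-H460. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The contrasts were each ASO against control, the second ASO of a candidate minus the first, and the mean of the candidate 42 ASOs minus the mean of the candidate 240 ASOs. Differences between lines were tested as interactions in a model of all 25 libraries (15 residual degrees of freedom, 14769 genes), as the response in A549 minus that in NCI-H460. Errors beside group means are standard deviations (SD), and those beside fold changes are standard errors (SE).

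Both ASOs of a candidate share control libraries, so their fold changes correlate with no effect at all. Unchanged groups compared with a common control group were simulated 100 times, with the control libraries drawn anew each time. The overlap that independent lists of the same sizes would give is printed beside the shared count. Almost no gene is called between unchanged groups, so their shared count near 0 was fixed by this setting. It is no reference for ASOs that each change many genes. The 3 or 2 control libraries cannot be split into groups of at least 2, so part of any excess may come from the shared controls. For the comparison of lines, which share no controls, fold changes of the 4 ASOs in A549 were correlated with those in NCI-H460 across 12760 genes. Genes are not independent replicates, so the spread of that comparison was taken from a jackknife over the 25 libraries.

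A set of 36 gene lists (pathways, stress responses, noncoding RNAs and markers of other cell types) was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Lists with at least 5 tested members were used, 34 in A549 and 32 in NCI-H460. The leukocyte and endothelial marker lists, and in NCI-H460 also the lung and squamous lists, had fewer and were not tested. camera with an estimated correlation and fry were run beside it.

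The groups, the tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names, per candidate and line, up to 6 raised and 6 lowered genes called with both ASOs whose libraries all lie on 1 side of the controls and whose higher group has a mean of at least 5 TPM, ranked by the smaller of the 2 changes. It adds the 2 largest changes each way per ASO, up to 4 members of lists called with both ASOs, the targets, and the 5 largest changes each way between candidates and between lines. Genes named outside this rule are said to have been chosen after their values were seen, and so were the genes given for differences between the 2 ASOs of a candidate. A further 3 genes, chosen either way, are not reported here. The target genes were taken from knowledge of the study and reference gene names, and not from the values. Positions are those of GENCODE gene models on hg38.

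Replicate numbers recur across groups, so the model was also fitted with the number as a block. The numbers were taken to pair libraries where a line has at least 3 numbers and every pair's deviations from the group means correlated above 0.1. In A549 this held for the comparisons of candidate 240 ASO1 with control (correlations of 0.17 to 0.41), of candidate 240 ASO3 with control (0.28 to 0.56), between the candidate 42 ASOs (0.13 to 0.41) and between the candidate 240 ASOs (0.24 to 0.48). It also held over the candidate 240 and control libraries of A549 together (0.17 to 0.56), and in no other A549 comparison. NCI-H460 has 2 numbers, so they were not taken to pair libraries, although both pairs between its candidate 42 ASOs correlated at 0.19. Nothing in the labels says what a number marks.

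Other alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 5 TPM, median-of-ratios scaling, fits of the compared groups alone, and each library left out in turn. Where that leaves a group of NCI-H460 with 1 library, that library is assumed to vary like the other groups. The comparisons of an ASO with control and the list tests were tested on simulated data with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. In A549 the test recovered 19.4% to 35.8%, 65.7% to 73.1% and 93.9% to 97% of these among 14740 genes, with 1 to 8 false calls per comparison. In NCI-H460 it recovered 29.9% to 38.8%, 67.2% to 74.6% and 92.4% to 97% among 13774 genes, with 6 to 13 false calls. A list shifted by 0.5 log2 was called in each of the 8 simulated comparisons, beside 0 to 3 unshifted lists.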

Results

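RNA was sequenced from 2 lung cancer lines, A549 (lung adenocarcinoma) and NCI-H460 (large cell carcinoma), 24 h after transfection with 25 nM of an antisense oligonucleotide (ASO). ASOs are short modified oligonucleotides that pair with an RNA and lead to its cleavage. The ASOs were aimed at 2 long noncoding RNAs (lncRNAs), called candidates 42 and 240, and each candidate was targeted by 2 ASOs of different sequence. Each line had a control ASO, candidate 42 ASO3 and ASO5, and candidate 240 ASO1 and ASO3, with n = 3 libraries per group in A549 and n = 2 in NCI-H460. The deposited values are rescaled TPM, from which the depth of a library is not known. Between 23879 and 27731 gene names had a value above 0 in a library, and mitochondrially encoded transcripts made up 6.48% to 11.1% of the signal.

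In A549 the first principal component (24.6% of the variance) placed all replicate 3 libraries below 0. Candidate 240 ASO3 replicate 3 lay farthest out, at -71.9, against -10.5 and -11.7 for the other libraries of its group. In NCI-H460 the first component (48.2%) placed the candidate 42 ASO3 libraries at 72.2 and 38.7, and the other 8 libraries between -28.5 and 3.1.

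The RNA taken as candidate 42 is AC107959.3, annotated as an antisense transcript on hg38 chromosome 8 from 23071377 to 23074488, on the minus strand. It stood at 7.61 ± 2.76 TPM (SD, n = 3) in A549 control libraries and at 0.65 ± 0.583 with ASO3, which is 8.55% of control (limma, log2 fold change -2.93, SE 0.37, adjusted p = 0.000211). With ASO5 it stood at 3.42 ± 1.21 TPM, or 45% of control, a difference that did not pass the test (adjusted p = 0.166). In NCI-H460 the control level was lower, 1.75 ± 0.825 TPM (SD, n = 2). AC107959.3 fell to 30.3% of it with ASO3 (0.529 ± 0.0176 TPM, limma log2 fold change -1.08, adjusted p = 0.0302), and stood at 95.5% with ASO5 (1.67 ± 0.3 TPM, adjusted p = 0.995). With candidate 240 ASO3, AC107959.3 stood at 340% of control in NCI-H460 (5.94 ± 0.846 TPM, adjusted p = 0.0346) and at 190% in A549 (14.4 ± 1.49 TPM, adjusted p = 0.123), and only the former passed. With candidate 240 ASO1 it stood at 252% in NCI-H460 (adjusted p = 0.927) and at 80.7% in A549 (adjusted p = 1). The NCI-H460 calls of AC107959.3 depended on single libraries. That with candidate 42 ASO3 was lost without control replicate 2 (log2 fold change -0.69, adjusted p = 0.204) or either ASO3 library (adjusted p = 0.102 and 0.0652), and that with candidate 240 ASO3 without any 1 of its 4 libraries (at most 1.95). Fitted without the filter, neither passed (adjusted p = 0.112 and 0.122). Because AC107959.3 is an antisense gene and the handling of strand is unknown, reads from the opposite strand cannot be told apart. TNFRSF10B, which encodes a death receptor and was looked at after the values were seen, stood at 63.1% of control in NCI-H460 with candidate 42 ASO3 (adjusted p = 0.000579) and at 90.6% in A549 (adjusted p = 0.587).

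**Figure D1:**
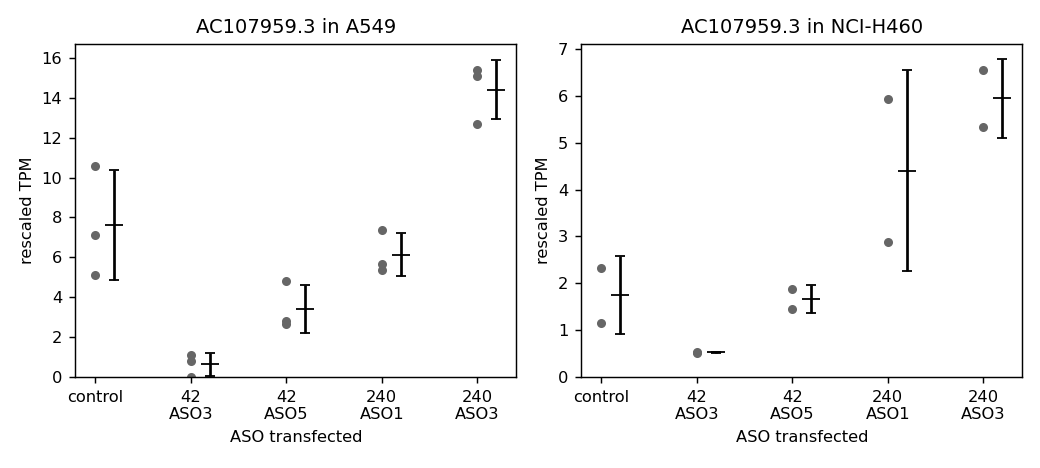
Rescaled TPM of AC107959.3 (y axis) per library for the control and the 4 ASOs (x axis), in A549 on the left and NCI-H460 on the right; points are libraries, and bars give the mean ± SD beside them. Candidate 42 ASO3 libraries lie lowest in each line, at means of 0.65 and 0.529.

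The RNA taken as candidate 240 is AC015712.6, a processed transcript on hg38 chromosome 15 from 100849831 to 100876836, on the plus strand. It lay under the filter of 1 TPM in both lines, at 0.347 ± 0.0757 TPM (SD, n = 3) in A549 control libraries and 0.078 ± 0.0407 (n = 2) in NCI-H460. In A549 it stood at 4.44% of control with ASO3 (0.0154 ± 0.0149 TPM) and at 53.4% with ASO1 (0.185 ± 0.0609 TPM). Fitted without the filter, limma gave an adjusted p of 0.00357 for ASO3 and of 1 for ASO1. In NCI-H460 the percentages were 59.6% with ASO3 and 111% with ASO1, at levels too low to tell from the spread of the controls. AC015712.1, chosen after its values were seen because it overlaps AC015712.6 on the same strand (100849561 to 100861756), was better measured in A549. It fell from 2.54 ± 0.377 TPM to 0.395 ± 0.15 with candidate 240 ASO3, 15.6% of control (log2 fold change -1.77, SE 0.25, adjusted p = 0.000311), and stood at 106% with ASO1. How reads were shared between these overlapping genes is uncertain.

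**Figure D2:**
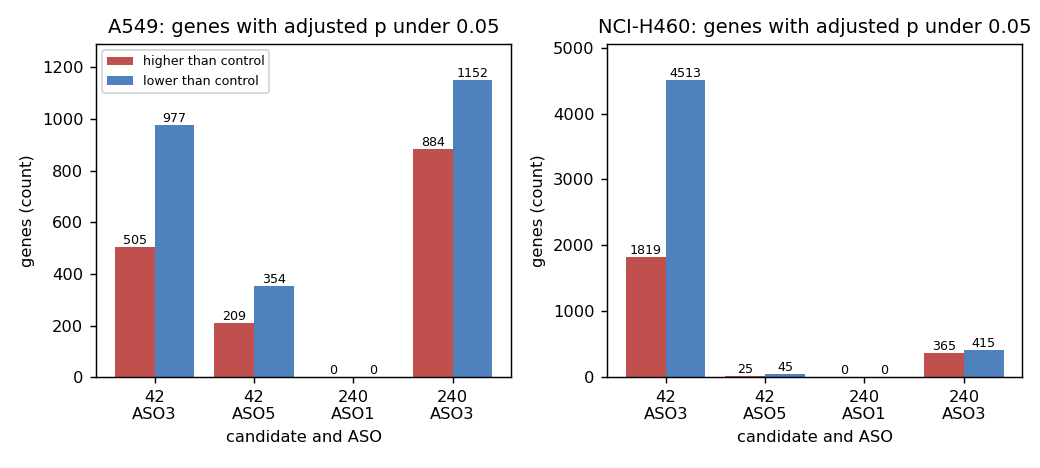
Number of genes (y axis) with an adjusted p under 0.05 in limma, higher (red) and lower (blue) than control, for each ASO (x axis) in A549 (left) and NCI-H460 (right, on its own scale). Counts run from 0 for candidate 240 ASO1 to 4513 lowered genes for candidate 42 ASO3 in NCI-H460.

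To determine which transcripts change with the ASOs against candidate 42, each was compared with the control ASO in A549. Among genes raised with both ASOs, PGF, a growth factor of the VEGF family, rose by a log2 fold change of 1.85 with ASO3 and 1.68 with ASO5 (SE 0.18 each, adjusted p = 3.54e-05 and 0.000281). NR4A2, an orphan nuclear receptor, rose by 1.66 and 1.27, and CEND1 by 1.57 and 2.17. APOE, which carries lipids between cells, went from 38.2 ± 12.7 TPM (SD, n = 3) to 261 ± 100 with ASO3 and 89.8 ± 22.2 with ASO5, with log2 fold changes of 2.73 and 1.24. PHOSPHO1, a phosphatase, rose by 1.76 and 1.33, and HES2, a transcriptional repressor, by 1.36 and 1.22. The genes lowered with both ASOs included LRMDA (log2 fold change -2.43 and -2.56), IMMP2L, which encodes a mitochondrial inner membrane peptidase (-2.56 and -1.60), and the lysine methyltransferase gene SMYD3 (-1.64 and -1.45). FARS2, the mitochondrial phenylalanyl-tRNA synthetase, changed by -1.34 and -1.85, the guidance factor SLIT3 by -2.02 and -1.33, and the bradykinin receptor BDKRB2 by -1.27 and -1.33. By the rule for naming them, the ASO libraries of each of these genes all lay on 1 side of the 3 controls. Of the lowered genes, LRMDA, IMMP2L, SMYD3, FARS2 and SLIT3 have long gene bodies (568149 to 1128545 bp), and BDKRB2 spans 39488 bp. These comparisons cannot tell loss of the target from other effects of the ASOs.

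Of 14740 genes tested in A549, limma called 1482 with candidate 42 ASO3 (505 higher, 977 lower) and 563 with ASO5 (209 higher, 354 lower). Fitted to the compared groups alone, the counts were 762 and 119. With the replicate block they were 3112 and 1533, with 599 genes called by both ASOs with the same sign. The replicate numbers fell short of the pairing rule here, at correlations of 0.09 to 0.39 (ASO3) and 0.02 to 0.32 (ASO5). In the main fit both ASOs called 203 genes with the same sign, 69 higher and 134 lower, and 10 with opposite signs. Independent lists of the sizes in the main fit would share 7.2 raised and 23.5 lowered genes. The 100 simulated pairs of unchanged groups shared 0, as almost no gene is called between such groups. The fold changes of the ASOs correlated across genes at r = 0.42, against 0.5 in the simulation, with a covariance of 0.071 against 0.0362. Since 3 controls cannot be split, part of this overlap may come from the shared control libraries. The ASO3 count was 955 and 832 without ASO3 replicate 4 and 5, while the ASO5 count was 326, 207 and 243 without ASO5 replicate 3, 4 and 5, and 308 and 305 without control replicate 4 and 5. The shared count of 203 became 130 and 119 without ASO3 replicate 4 and 5, 127, 81 and 88 without ASO5 replicate 3, 4 and 5, and 113 and 106 without control replicate 4 and 5. The APOE call with ASO5 was lost without any of 5 of the 6 libraries (log2 fold changes of 1.05 to 1.37) and after median-of-ratios scaling (adjusted p = 0.0533), that of HES2 without ASO5 replicate 4 (1.10), and that of BDKRB2 without ASO5 replicate 4 or 5.

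Gene lists called by camera with both candidate 42 ASOs in A549 were p53 targets, apoptosis regulators, heat shock genes and cholesterol biosynthesis, all higher, and NRF2 targets, lower. The cholesterol biosynthesis list, which also holds fatty acid genes such as FASN, stood out with ASO5. There 11 of 29 members rose and 0 fell (adjusted p = 2.06e-12, and 0.0458 with an estimated correlation). With ASO3, 4 rose and 1 fell (adjusted p = 0.00137, and adjusted p = 0.253 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell with ASO3 and 20 rose and 1 fell with ASO5. IDI1, an isoprenoid enzyme gene, rose by log2 fold changes of 0.70 and 0.69, and FASN, the fatty acid synthase gene, by 0.98 and 0.86. INSIG1 rose with ASO3 by 0.62, and its change with ASO5 did not pass (0.50, adjusted p = 0.0649). Of 30 p53 targets, 4 rose and 1 fell with ASO3 (adjusted p = 0.0103, and adjusted p = 0.0956 with an estimated correlation), and 3 rose and 0 fell with ASO5 (adjusted p = 0.000293, and 0.0218 with an estimated correlation). Over the list alone the counts were 4 and 1, and 5 and 1. CCNG1 (0.39 and 0.49) and BTG2 (0.52 and 0.64) rose with both ASOs, MDM2, the ubiquitin ligase of p53, rose with ASO3 (0.79), and CDKN1A, which encodes the cell cycle inhibitor p21, rose with ASO5 (0.65).

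The NRF2 targets, genes of oxidative stress defence, fell in 8 of 29 cases with ASO3 and in 3 with ASO5 in A549, with none risen (adjusted p = 0.00012 and 0.00987). After median-of-ratios scaling 5 and 1 fell. With an estimated correlation the list gave adjusted p = 0.122 and 0.513, and adjusted over the list alone 11 and 5 fell. TRIM16L changed by log2 fold changes of -0.69 and -0.41 and AKR1B10 by -0.46 and -0.52, while EPHX1 (-0.42) and AKR1C2 (-0.51) fell with ASO3. Heat shock genes gave adjusted p = 0.000211 and 0.00987, and adjusted p = 0.4 and 0.611 with an estimated correlation. Of 17 heat shock genes, 3 rose with ASO3, HSPH1 by 0.59, and 0 with ASO5 (8 and 0 over the list alone). HSPA4 (0.32 and 0.41) and STIP1 (0.26 and 0.26) were higher without passing. HSPA1A was higher by 0.88 with ASO5 without passing, and by 0.15 without control replicate 5. Of 27 apoptosis regulators, 3 rose with ASO3 and 1 with ASO5, over the list alone also 3 and 1 (adjusted p = 0.0181 and 0.0416, and adjusted p = 0.122 and 0.263 with an estimated correlation). The death receptor gene TNFRSF10A rose with ASO5 (0.54), and FAS (0.31 and 0.28), CASP10 (0.37 and 0.41) and BAK1 (0.31 and 0.25) were higher without passing. No list of either candidate in either line kept its call for both ASOs with an estimated correlation. Without control replicate 3, 8 lists instead of 5 were called with both ASOs. Single member calls were less stable: those of CCNG1, BTG2 and AKR1B10 with both ASOs, of MDM2, HSPH1, EPHX1 and AKR1C2 with ASO3, and of FASN with ASO5 were lost without each of at least 4 of the 6 libraries in turn. IDI1 with ASO5 lost its call without 2 of the 6, and INSIG1 with ASO3 and TRIM16L with ASO5 without 1. After median-of-ratios scaling AKR1B10 lost its calls (adjusted p = 0.0643 and 0.0665), as did EPHX1 with ASO3 (0.0628).

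The ASOs of candidate 42 also differed from each other in A549. THSD4, which encodes an extracellular matrix protein, stood at 8.96 ± 0.663 TPM with ASO3 and 42.1 ± 6.02 with ASO5 (SD, n = 3), against 91.9 ± 41.1 in controls. DHX32, a helicase gene, stood at 47.5 ± 1.52 TPM with ASO3 and 10.1 ± 1.65 with ASO5, against 44.2 ± 8.16 in controls. ASO5 minus ASO3 gave log2 differences of 2.17 (adjusted p = 0.0027) for THSD4 and -2.20 (adjusted p = 6.67e-06) for DHX32, and of 1.89 (adjusted p = 0.00535) for AC107959.3. AC091729.2 rose with ASO3 (log2 fold change 3.34), AL645929.2 with ASO5 (2.42), and SCARNA20, listed at 0 in controls, stood at 5.74 ± 1.6 TPM with ASO5. AL645929.2 lost its call without control replicate 3 (1.92, adjusted p = 0.0798) or ASO5 replicate 3 or 4 (2.09 and 2.48). With ASO3, 9 of 21 genes of the unfolded protein response fell (13 over the list alone) and 0 rose (adjusted p = 3.02e-08, and adjusted p = 0.0837 with an estimated correlation). Of 23 TGF-beta targets 9 fell (12 over the list alone), and of 24 interferon-stimulated genes 7 rose (7 over the list alone), with adjusted p = 9.93e-06 and 0.00012, and adjusted p = 0.0956 and 0.122 with an estimated correlation. These lists and their genes were picked out after the values were seen. The endoplasmic reticulum chaperone gene HSPA5 changed by -0.76 with ASO3, PDIA4 by -0.84 and the collagen gene COL4A1 by -1.59, while OAS1, an antiviral enzyme gene, rose by 1.10.

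Between the candidate 42 ASOs, limma called 1570 of 14740 A549 genes (888 higher with ASO5, 682 lower). Replicate numbers paired these libraries, and with the replicate block 3152 genes were called (1759 higher, 1393 lower). The count was 968 and 908 without ASO3 replicate 4 and 5, and 940 and 967 without ASO5 replicate 4 and 5.

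The same question was asked of candidate 240 in A549. With ASO3, the replication helicase gene MCM6 fell from 47.2 ± 5.05 TPM to 5.00 ± 0.732 (SD, n = 3, log2 fold change -3.12, SE 0.11, adjusted p = 2.61e-09). NR3C1, which encodes the glucocorticoid receptor, fell from 27.4 ± 10.3 to 2.54 ± 1.02 TPM (-3.18). MIR641, a gene of 99 bp whose value may rest on few reads, went from 5.25 ± 2.42 TPM to being listed at 0. LGALS7, a galectin gene, rose by 2.60 and AL355312.3 by 2.63. None of these reached the threshold with ASO1, with which limma called 0 of 14740 genes (267 had an unadjusted p under 0.05, and the authors' deposited table has 0 with a q-value under 0.05). With ASO3 limma called 2036 genes (884 higher, 1152 lower), or 3696 with the replicate block (1636 higher, 2060 lower). Hence 0 genes were called with both ASOs, and the simulated pairs shared at most 1. Without the filter, 5 genes were called with ASO1 and 4 with both. The fold changes of the candidate 240 ASOs correlated across genes at r = 0.17, against 0.5 in the simulation, with a covariance of 0.0217 against 0.0362. The simulated groups were unpaired, while replicate numbers paired these libraries, so the simulated values are only a rough reference.

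Cholesterol biosynthesis was the list called with both candidate 240 ASOs in A549. With ASO3, 12 of 29 members rose (16 over the list alone, with 1 fallen) and with ASO1 0 did (0 over the list alone). The adjusted p was 1.82e-06 with ASO3 and 0.0444 with ASO1, and adjusted p = 0.0935 and 0.898 with an estimated correlation. The sterol enzyme genes ACAT2, SQLE, DHCR7 and FDFT1 rose with ASO3 by log2 fold changes of 0.60, 0.56, 0.48 and 0.45, and stood at 0.15, 0.15, 0.13 and 0.11 with ASO1. This shared call depended on single libraries: without control replicate 5, ASO1 replicate 4 or 5, or ASO3 replicate 4, 0 lists were called with both ASOs, and without control replicate 3 and 4 there were 4 and 2.

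Other A549 lists called with candidate 240 ASO3 were picked out after the values were seen. Of 30 p53 targets 10 rose and 0 fell (12 over the list alone), a call that held with an estimated correlation (adjusted p = 7.34e-06, and 0.00866 with the estimate). TP53I3 rose by a log2 fold change of 1.23, the proapoptotic BBC3 by 0.96 and CDKN1A by 0.66. Of 34 genes of G1/S and DNA replication 12 fell, and of 36 genes of G2/M and mitosis 13 fell, with 0 risen in either (16 and 20 fell over the list alone). Their adjusted p was 1.82e-08 and 2.23e-08, and adjusted p = 0.0935 for each with an estimated correlation. With ASO1 the G2/M list was called in the opposite direction, with 33 of 36 members higher and 0 called (adjusted p = 0.00049, and 0.666 with an estimated correlation). With ASO3 the lowered genes of the G1/S list included, beside MCM6, the DNA polymerase gene POLA1 (-1.84). Those of the G2/M list included the centromere histone gene CENPA (-0.81) and the mitotic kinase gene AURKA (-0.47). Of 24 interferon-stimulated genes 11 rose (14 over the list alone), OASL by 2.06, IFIT3 by 0.95 and ISG15 from 13.7 ± 3.18 to 59.2 ± 27.8 TPM, and of 21 genes of the unfolded protein response 10 fell (11 over the list alone), PDIA4 by a change of -0.69 and SYVN1 of -0.63. These lists had adjusted p = 4.12e-07 and 7.34e-06, and adjusted p = 0.0935 for each with an estimated correlation.

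Between the candidate 240 ASOs in A549, MCM6 differed by a log2 value of -3.26 (ASO3 minus ASO1, adjusted p = 1.44e-09), NR3C1 by -3.32, POLA1 by -1.86 and the small GTPase gene RALA by -2.54. AC107959.3 differed by 1.17 (adjusted p = 0.0463), a call lost without any 1 of the 6 libraries (1.09 to 1.3). limma called 2465 genes (1068 higher with ASO3, 1397 lower), and 4411 with the replicate block (1943 higher, 2468 lower), since replicate numbers paired these libraries too. Without ASO1 replicate 4 and 5 the count was 1585 and 1639.

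Set against each other without the controls, the A549 groups of candidate 42 had higher MCM6 (log2 difference 1.49, adjusted p = 5.06e-07) and RALA (1.48) than those of candidate 240, with RALA at 20.6 and 21.1 TPM for candidate 42 ASO3 and ASO5 and at 17.9 and 2.74 for candidate 240 ASO1 and ASO3. Candidate 42 groups had lower AC107959.3 (-2.32, adjusted p = 0.000162), DENND1A (-1.38), which encodes a membrane traffic regulator, PITRM1 (-1.28), a mitochondrial peptidase gene, AC119751.6 (-1.78) and LRMDA (-1.24). PITRM1 stood at 6.79 ± 1.33 TPM with candidate 42 ASO3 and between 40.2 and 51.3 in the other ASO groups, and MIR641 (2.61), MIR2116 (2.31) and AC091729.2 (2.04) were higher with candidate 42. In all limma called 1194 genes, 502 higher and 692 lower with candidate 42. With the replicate block, whose numbers fell short of the pairing rule here (correlations of 0.06 to 0.48), it called 2799. Several of these differences rest on a single ASO of a candidate.

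In NCI-H460 candidate 42 ASO3 gave the widest response of the 8 comparisons with control. TEAD1, a transcription factor of the Hippo pathway, fell from 21.1 ± 0.279 TPM (SD, n = 2) to 1.17 ± 0.466 (log2 fold change -3.72, SE 0.19, adjusted p = 2.43e-05). In the values as deposited, the median of all 13774 genes was -0.20 on the log2 scale with this ASO, and median-of-ratios scaling removes this shift. Fold changes of the candidate 42 ASOs against control in this line are therefore given after that scaling from here through the gene lists. Values with libraries left out and values in comparisons with A549 are as deposited unless scaling is named. APOE rose by 2.73 with ASO3 and 1.68 with ASO5, CYSRT1 by 1.68 and 1.49, CEND1 by 1.43 and 2.04, GKN2 by 1.60 and 2.33 and the potassium channel gene KCNF1 by 2.13 and 1.16, while SNORA11, listed at 0 in controls, stood at 3.27 ± 0.797 and 7.96 ± 1.61 TPM. The kinase gene HIPK2 fell with both ASOs (-1.97 and -1.10), as did PLCB1, a phospholipase gene (-1.14 and -1.07), GOLM2 (-0.94 and -0.99), LINC01035 (-1.87 and -1.26), AC009119.1 (-1.48 and -1.14) and AC109466.1 (-1.21 and -1.10). With ASO5, AC107959.3 stood at 95.5% of control in this line. A change shared by both ASOs here can therefore not be read as an effect of losing the target. RBM6, an RNA-binding protein gene, fell with ASO5 (-1.32). AC011511.4 and AL583722.1, listed at 0 in controls, stood at 12.7 ± 9.26 and 21 ± 25.7 TPM with ASO3, and the pseudogene BZW1P2 went from 56.8 ± 6.19 to 13.3 ± 18.7 TPM, with libraries of a group far apart in each case. BZW1P2 shares sequence with its parent gene, so its value is uncertain, and its call was lost under median-of-ratios scaling (adjusted p = 0.0512), as was that of KCNF1 with ASO5 (adjusted p = 0.0529).

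With ASO3 limma called 6332 of 13774 NCI-H460 genes (1819 higher, 4513 lower), and 6451 after median-of-ratios scaling (3229 higher, 3222 lower). With ASO5 it called 70 (25 higher, 45 lower), and 2093 genes had an unadjusted p under 0.05, while the authors' deposited table has 9192 genes with a q-value under 0.05 for ASO3 and 0 for ASO5. Both ASOs called 58 genes with the same sign (20 higher, 38 lower) and 1 with opposite signs. Fitted to the candidate 42 and control libraries alone, limma called 1 gene with both. Independent lists would share 3.3 and 14.7. Simulated pairs shared at most 1, as almost no gene is called between unchanged groups. The fold changes of the ASOs correlated across genes at r = 0.55, against 0.5 in the simulation, with a covariance of 0.1288 against 0.0313, and part of this may come from the 2 shared controls. Without any 1 of the 4 ASO5 and control libraries the ASO5 count was 0, so each ASO5 call named above and the shared count rest on every library. The shared count was 261 and 325 without ASO3 replicate 1 and 2, and the ASO3 count was 4103 and 3698 without control replicate 1 and 2. BZW1P2 and AL583722.1 lost their calls without either control library (log2 fold changes of -3.85 and -4.07, and of 4.53 each).

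Lists called with both candidate 42 ASOs in NCI-H460 were heat shock genes, cholesterol biosynthesis and nuclear OXPHOS subunits, all higher, and YAP/TEAD targets, lower. Since ASO5 left the target at 95.5% of control, these shared calls cannot be read as effects of its loss. With ASO3, 17 of 22 YAP/TEAD targets fell and 0 rose (13 and 1 after median-of-ratios scaling, 18 and 1 over the list alone), and with ASO5 0 passed (3 fell over the list alone). ASAP1 changed by -2.14 with ASO3 after this scaling, RBMS3 by -1.39 and IGFBP3 by -0.86, against -0.61, -0.94 and -0.73 with ASO5, which did not pass. CCN2, a matricellular protein gene, was called as deposited (-0.52, adjusted p = 0.0162) and not after scaling (-0.31, adjusted p = 0.11). The list's adjusted p was 0.000235 with ASO3 and 0.0485 with ASO5, and adjusted p = 0.656 and 0.59 with an estimated correlation. Of 28 genes of the cholesterol biosynthesis list, which also holds fatty acid genes such as FASN, 10 rose and 4 fell with ASO3. Over the list alone 11 rose and 4 fell, and after scaling 15 and 1. MVD rose by 1.47, FASN by 1.43, FADS2 by 0.93 and NSDHL by 0.85. With ASO5 0 passed (2 rose over the list alone). The adjusted p was 0.00391 and 0.0315, and adjusted p = 0.656 and 0.481 with an estimated correlation. Of 17 heat shock genes 5 rose and 1 fell with ASO3 (5 and 1 over the list alone, 12 and 0 after scaling), including the cochaperone genes AHSA1 (0.82), FKBP4 (0.69), STIP1 (0.60) and HSPA4 (0.57), and 0 passed with ASO5 (5 rose over the list alone). Here the adjusted p was 0.00438 and 3.79e-05, and adjusted p = 0.656 and 0.481 with an estimated correlation.

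Of 39 nuclear genes of oxidative phosphorylation, 12 rose and 1 fell with ASO3 in NCI-H460 (8 and 1 over the list alone, 23 and 1 after median-of-ratios scaling) and 0 passed with ASO5 (0 over the list alone). The adjusted p was 1.97e-05 and 0.00816, and adjusted p = 0.656 and 0.707 with an estimated correlation. NDUFB10 (0.79), NDUFS3 (0.75) and COX5A (0.59) rose with ASO3 after scaling. HSPA4 lost its call as deposited without either control library (0.32 and 0.39), COX5A without either control library or ASO3 replicate 1 (0.42, 0.34 and 0.20), NDUFB10 without control replicate 2 (0.53) and CCN2 without control replicate 1 or ASO3 replicate 2 (-0.40 and -0.47). Without ASO5 replicate 1 or ASO3 replicate 2, 2 of these lists were called with both ASOs, and without control replicate 1 the heat shock list alone of them.

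The candidate 42 ASOs differed at many NCI-H460 genes. TEAD1 stood at 15.6 ± 2.44 TPM with ASO5 against 1.17 ± 0.466 with ASO3 (SD, n = 2, log2 difference 3.11 after median-of-ratios scaling), EPHA5, an ephrin receptor gene, at 7.54 ± 1.53 against 0.968 ± 0.183 (2.27), and AC107959.3 at 1.67 ± 0.3 against 0.529 ± 0.0176. The difference of AC107959.3 passed as deposited (1.07, adjusted p = 0.0405) and not after scaling (0.93, adjusted p = 0.0659), nor without any 1 of the 4 libraries (0.93 to 1.21 as deposited). FASN was lower with ASO5 (-1.09). limma called 4588 genes (3814 higher with ASO5, 774 lower), and 4168 after this scaling (2178 higher, 1990 lower). The count was 2840 without ASO3 replicate 1, and 2958 and 1980 without ASO5 replicate 1 and 2.

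With candidate 240 ASO3 in NCI-H460, NECTIN4, a cell adhesion gene, rose from 0.764 ± 0.0294 to 6.01 ± 0.421 TPM (SD, n = 2, log2 fold change 2.36, SE 0.23, adjusted p = 0.00208), and GKN2 rose by 2.37. PTPRG, a receptor phosphatase gene, fell from 6.98 ± 0.481 to 0.869 ± 0.309 TPM (-2.47, adjusted p = 0.00227), and CAP2, an actin regulator gene, from 9.16 ± 0.175 to 1.58 ± 0.618 (-2.25). MCM6 fell from 56.2 ± 0.53 to 12.1 ± 2.45 TPM (-2.19, adjusted p = 0.000493). With ASO1 limma called 0 of 13774 genes (493 had an unadjusted p under 0.05, the smallest adjusted p was 0.0609, and the authors' deposited table has 0 with a q-value under 0.05). With ASO3 it called 780 (365 higher, 415 lower), so 0 were shared, and the simulated pairs shared at most 1. Fitted without the filter, 44 genes were called with ASO1 and 22 with both. Across genes the fold changes correlated at r = 0.49, against 0.5 in the simulation, with a covariance of 0.0584 against 0.0312. The ASO3 count was 125 and 76 without control replicate 1 and 2, and 392 and 110 without ASO3 replicate 1 and 2, and without control replicate 2 the ASO1 count and the shared count were 2 each.

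Mitochondrially encoded transcripts were the list called with both candidate 240 ASOs in NCI-H460, although 0 of the 13 passed as single genes with either ASO, also over the list alone. Log2 fold changes with ASO1 and ASO3 were 0.32 and 0.41 for MT-CYB, 0.35 and 0.37 for MT-ATP6, 0.36 and 0.25 for MT-ND1, and 0.38 and 0.33 for MT-CO3. The adjusted p was 2.22e-06 and 0.0137, and adjusted p = 0.943 and 0.604 with an estimated correlation, and 3 lists were called without ASO1 replicate 1. Picked out after the values were seen, 9 of 29 p53 targets rose with ASO3 and 0 fell (12 over the list alone), which held with an estimated correlation (adjusted p = 3.19e-07, and 0.0416 with the estimate). FDXR rose by 1.49, CDKN1A by 0.96 and TP53I3 by 1.01. Of 26 interferon-stimulated genes 8 rose with ASO3 (11 over the list alone), IRF9 by 1.56, OASL by 2.45 and ISG15 by 1.87 (adjusted p = 3.21e-06, and adjusted p = 0.266 with an estimated correlation). ISG15 lost its call without control replicate 2 (1.60) or ASO3 replicate 2 (1.85).

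Between the candidate 240 ASOs in NCI-H460, MCM6 differed by a log2 value of -2.12 (ASO3 minus ASO1, adjusted p = 0.000668), FDXR by 1.37 and OASL by 2.41. limma called 402 genes, 143 higher and 259 lower with ASO3. Without ASO1 replicate 1 and 2 the count was 53 and 52, and without ASO3 replicate 1 and 2 it was 179 and 59.

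Set against candidate 240 in NCI-H460, the candidate 42 groups had lower AC107959.3 (-1.83 after median-of-ratios scaling), RBM14-RBM4 (-1.47), a readthrough gene whose reads overlap its neighbours, LINC02615 (-1.53), MIR4442 (-1.59) and MIR4502 (-2.26). SNORA11 (2.50), the ion channel gene ZACN (2.20), AL139317.3 (2.18) and AC011511.4 (2.31) were higher with candidate 42. Such differences can rest on a single ASO: AL139317.3 stood at 12.4 ± 8.76 TPM with ASO3 and is listed at 0 with ASO5, AC011511.4 stood at 12.7 ± 9.26 and 0.248 ± 0.351, and MIR4442 is listed at 0 with ASO3 and stood at 4.82 ± 1.79 with ASO5 (SD, n = 2). limma called 1604 genes, 273 higher and 1331 lower with candidate 42, and 1297 after this scaling, 482 higher and 815 lower. The count was 4171 without candidate 42 ASO3 replicate 2, 464 and 812 without candidate 42 ASO5 replicate 1 and 2, 487 and 515 without candidate 240 ASO1 replicate 1 and 2, and 534 and 996 without candidate 240 ASO3 replicate 1 and 2. MIR4502 lost its call without 6 of the 8 libraries in turn, MIR4442 and LINC02615 without 3, and AC011511.4 without 2, at log2 differences of -2.53 to -1.87, -1.71 to -1.42, -1.53 to -1.38 and 1.96 to 1.99.

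Whether the lines responded differently was tested as an interaction, the mean response to a candidate's ASOs in A549 minus that in NCI-H460. COL18A1, a basement membrane collagen gene, differed for both candidates, by log2 values of -1.50 for candidate 42 (SE 0.14, adjusted p = 1.86e-05) and -1.03 for candidate 240 (SE 0.14, adjusted p = 0.0121). In A549 it stood at 30.2 ± 2.62 TPM (SD, n = 3) with candidate 42 ASO3, a log2 fold change of -1.93 against control, and at 83.5 ± 5.79 with ASO5 (-0.47). In NCI-H460 it stood at 3.00 ± 0.243 TPM (n = 2) in controls and 2.98 ± 0.272 with ASO3. For candidate 240 the difference came mostly from ASO3. COL18A1 changed in A549 by -0.02 with ASO1 and -1.42 with ASO3, and in NCI-H460 by 0.26 and 0.35. Genes with lower fold changes in NCI-H460 than in A549 over the candidate 42 ASOs were CDH13, an adhesion gene (difference 2.09), EPHA5 (1.78), FRMD6, a Hippo pathway gene (1.69), MIR4442 (2.77) and the pseudogene PKD1P5 (2.11). In NCI-H460 this came mostly from ASO3, with log2 fold changes, as deposited, of -2.33 with ASO3 and -0.24 with ASO5 for FRMD6, -3.49 and -0.12 for MIR4442, and -3.23 and -0.43 for PKD1P5. In A549 the same genes stood at 0.32 and 0.49, 0.69 and 1.24, and 0.24 and 0.33. Those with lower fold changes in A549 than in NCI-H460 were GPR39 (-1.78), SLIT3 (-1.68), PMEPA1, a TGF-beta response gene (-1.59), and G0S2 (-1.57). Several of them are near 0 in 1 line, where a change could not be measured: CDH13 stood at 0.0188 ± 0.0164 TPM in A549 controls and 80.9 ± 7.69 in NCI-H460 controls, and SLIT3 at 8.45 ± 0.941 and 0.0103 ± 0.0146.

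Of 14769 genes, limma called 188 for candidate 42 (122 with a higher and 66 with a lower fold change in A549 than in NCI-H460) and 1 for candidate 240, COL18A1. With the replicate block the counts were 2650 (1793 higher, 857 lower) and 22. After median-of-ratios scaling the candidate 42 count was 182 (77 higher, 105 lower). By ASO the counts were 2909 for candidate 42 ASO3 (2286 higher and 623 lower, or 2549 with 1166 and 1383 after this scaling), 5 for ASO5, 179 for candidate 240 ASO3 (58 and 121), and 0 for candidate 240 ASO1, where 410 had an unadjusted p under 0.05. The 5 genes for ASO5, named after their values were seen, were COL18A1 (-1.09), CLDN2 (-1.35), ACSS2 (0.90), RAB3B (1.31) and AC044860.1 (1.59). Of these, ACSS2 lost its call after median-of-ratios scaling (adjusted p = 0.0663), and ACSS2, AC044860.1, COL18A1 and CLDN2 each without at least 3 of the 10 libraries in turn. The candidate 42 count depended on each of 11 libraries. It was 13 and 14 without NCI-H460 control replicate 1 and 2, 65 and 823 without NCI-H460 ASO3 replicate 1 and 2, and 61 and 105 without NCI-H460 ASO5 replicate 1 and 2. It was 78 without A549 control replicate 3, 105 and 93 without A549 ASO3 replicate 4 and 5, and 119 and 95 without A549 ASO5 replicate 4 and 5. The COL18A1 call for candidate 240 was lost without A549 control replicate 3 or 4, NCI-H460 control replicate 2 or NCI-H460 ASO1 replicate 1, at differences of -0.95, -1.03, -0.96 and -0.98, and the count was 3 without A549 ASO3 replicate 3 and 2 without NCI-H460 control replicate 1. For candidate 42, MIR4442 and PKD1P5 lost their calls without 12 of 15 libraries in turn, G0S2 without 10, FRMD6 without 5, GPR39 without 4, SLIT3 without 2 and PMEPA1 without 1.

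Responses to the same ASO were then compared between the lines, which share no control libraries. In the values as deposited, the same genes fell far with candidate 240 ASO3 in A549 and NCI-H460: MCM6 by log2 fold changes of -3.12 and -2.19, NR3C1 by -3.18 and -1.91, CAP2 by -2.78 and -2.25, BAZ2B by -2.98 and -1.96 and PTPRG by -2.46 and -2.47. With candidate 42 ASO5 the genes lowered in both lines included RBM6 (-1.93 and -1.31), FCHSD2 (-1.93 and -1.31), FARS2 (-1.85 and -1.16), GALNT12 (-1.36 and -1.13) and REPS1 (-1.81 and -1.08). These 10 genes were chosen after their values were seen. Each of the ASO5 calls in NCI-H460 was lost without any 1 of the 4 libraries compared. Among 12760 genes tested in both lines, 234 were lowered by candidate 240 ASO3 in both, against 29.9 for independent lists of 1022 and 373 genes, and 133 were raised, against 17.9. Candidate 42 ASO5 lowered 28 genes in both lines (0.9 for independent lists) and raised 8 (0.3), and candidate 42 ASO3 lowered 501 (282.4) and raised 149 (54.7).

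Across the 12760 genes, which are not independent replicates, log2 fold changes in the lines correlated at r = 0.52 for candidate 240 ASO3, 0.33 for candidate 42 ASO5, 0.21 for candidate 42 ASO3 and -0.23 for candidate 240 ASO1 (Spearman rho 0.5, 0.33, 0.13 and -0.34). The mean r of pairs with the same ASO was 0.208 (jackknife SE 0.215), the highest of the 24 arrangements of ASO labels (one-sided exact permutation p = 0.0417, the smallest these can give). The mean r of the pairs of ASOs against the same candidate exceeded that of pairs against different candidates by 0.06, with a jackknife SE of 0.046, and this was the highest of 6 arrangements, which cannot give a p under 0.1667 (one-sided exact permutation). That excess lay in the pairs with the same ASO, since pairs with the other ASO of the candidate had a mean r of 0.015 and pairs of different candidates 0.052. Candidate 240 ASO3 in A549 correlated with candidate 42 ASO3 in NCI-H460 at r = 0.32, above the 0.21 of the latter ASO in both lines.

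**Figure D3:**
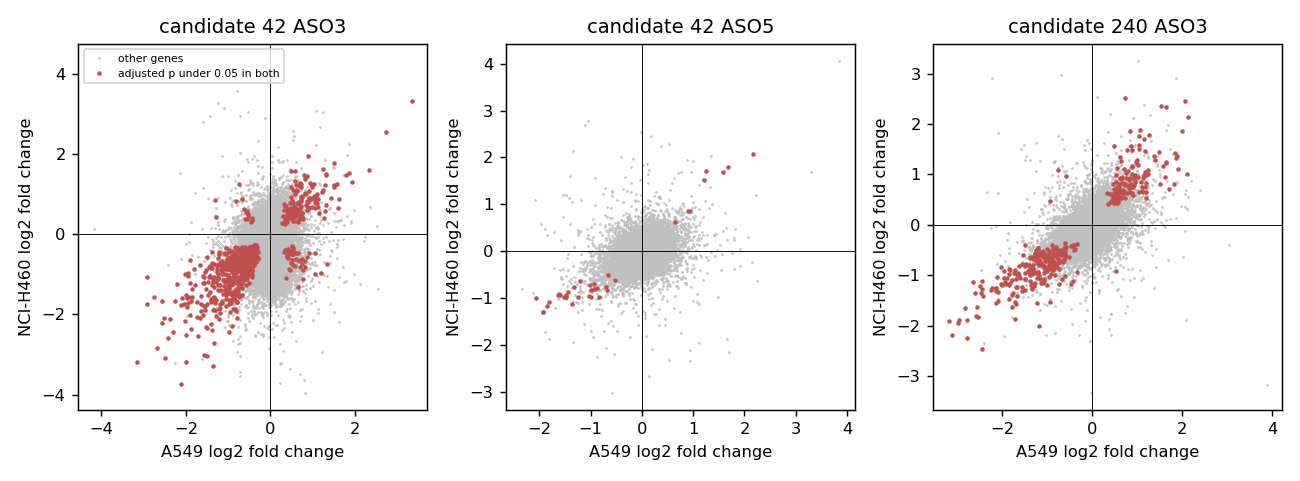
Log2 fold change against control in A549 (x axis) and NCI-H460 (y axis) for each gene tested in both lines, for candidate 42 ASO3, candidate 42 ASO5 and candidate 240 ASO3; red points have an adjusted p under 0.05 in both lines. Red points gather in the lower left and upper right, with 234 genes lowered in both lines by candidate 240 ASO3.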

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

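Of the tests below, those of scaling, single libraries and target loss for the broad NCI-H460 response were chosen after the result was seen, as were the scaling and single-library checks of the differences between lines. Each result in this part is listed because an interaction test of the difference between the lines passed the threshold. Values are log2 fold changes in A549 minus those in NCI-H460. Groups held 2 or 3 libraries, too few to test a single library as an outlier.

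The mean response to candidate 42 differed between lines for 188 genes, the response to its ASO3 for 2909 and that to its ASO5 for 5. For candidate 240 the mean response differed for 1 gene (COL18A1) and the response to ASO3 for 179. These counts depend on single libraries. For the mean response to candidate 42 the count was 13 and 14 without NCI-H460 control replicate 1 and 2, 65 and 823 without NCI-H460 ASO3 replicate 1 and 2, and 61 and 105 without NCI-H460 ASO5 replicate 1 and 2. It was 78 without A549 control replicate 3, 105 and 93 without A549 ASO3 replicate 4 and 5, and 119 and 95 without A549 ASO5 replicate 4 and 5. For candidate 42 ASO5 it was 1 without NCI-H460 control replicate 1 or 2 or ASO5 replicate 1, 2 without A549 ASO5 replicate 5, and 3 without A549 control replicate 3 or 4 or ASO5 replicate 3. For candidate 42 ASO3 the count was 1044 and 761 without NCI-H460 control replicate 1 and 2, 275 and 3801 without NCI-H460 ASO3 replicate 1 and 2, 1348 without A549 control replicate 3, and 1557 and 1629 without A549 ASO3 replicate 4 and 5. For candidate 240 ASO3 it was 60 and 47 without NCI-H460 control replicate 1 and 2, 68 and 74 without NCI-H460 ASO3 replicate 1 and 2, and 114, 269, 104 and 106 without A549 control replicate 4, ASO3 replicate 3, ASO3 replicate 4 and ASO3 replicate 5.

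In NCI-H460, candidate 42 ASO3 gave the broadest response of the 4 ASOs (6332 genes called). Scaling of the deposited values is argued against as the whole cause, since 6451 genes were called with median-of-ratios scaling, and so is 1 of the 2 ASO3 libraries, since at least 4273 were called with either left out (3698 without control replicate 2). Transcript-length bias between libraries is argued against too, with 6107 genes called after a length trend was removed, against 6173 before among 13319 genes with a known length, but fold changes followed genomic span more closely (Spearman rho -0.48, against -0.09 for transcript length; median spans of 63.1 kb for lowered and 9.59 kb for raised genes), and that trend was not removed. Loss of the target RNA cannot be told apart from other effects of this ASO, because ASO5 left the target at 95.5% of control in NCI-H460. With ASO5 the genes called with ASO3 moved by a median of 0.19 in the same direction, against 0.7 with ASO3, and the shared controls alone push that median upwards.

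With candidate 42 ASO3 the difference was positive for PHOSPHO1 (1.63), NR4A2 (1.30), HES2 (1.09), CCNG1 (0.49), TNFRSF10A (0.57), TNFRSF10B (0.52), FAS (1.19), LINC01035 (1.93), AC009119.1 (1.81), AC109466.1 (1.37), PLCB1 (1.36), GOLM2 (1.04), BZW1P2 (4.79), TEAD1 (1.61), IGFBP3 (0.88), CCN2 (0.94), OAS1 (0.93) and IFIT3 (0.63). It was negative for SLIT3 (-2.01), BDKRB2 (-1.24), AC107959.3 (-1.85), KCNF1 (-1.91), AL583722.1 (-4.53), AC011511.4 (-4.23), MVD (-0.84) and COL4A2 (-1.26). The BZW1P2 difference was 1.91 without NCI-H460 ASO3 replicate 1 and 7.67 without NCI-H460 ASO3 replicate 2. These values include a shift of -0.20 in the median of all genes in NCI-H460 with this ASO.

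With candidate 42 ASO5 the difference was 0.90 for ACSS2, 1.31 for RAB3B, 1.59 for AC044860.1, -1.09 for COL18A1 and -1.35 for CLDN2. For the mean response to candidate 42 it was 2.77 for MIR4442, 2.11 for PKD1P5, 2.09 for CDH13, 1.78 for EPHA5, 1.69 for FRMD6, -1.78 for GPR39, -1.68 for SLIT3, -1.59 for PMEPA1, -1.57 for G0S2 and -1.50 for COL18A1. With candidate 240 ASO3 it was 2.60 for LGALS7, 0.69 for SQLE, -2.31 for GKN2, -0.93 for MCM6, -0.54 for CENPA, -0.54 for AURKA, -0.64 for SYVN1 and -1.06 for IRF9. For the mean response to candidate 240 it was -1.03 for COL18A1, a call lost without A549 control replicate 3 or 4, NCI-H460 control replicate 2 or NCI-H460 ASO1 replicate 1 (-1.10 to -0.95 over the libraries left out). The A549 fold change of COL18A1 was -0.02 with candidate 240 ASO1 and -1.42 with ASO3.

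Some of these genes did not pass the 1 TPM filter in 1 line, where a change could not be measured, so their differences restate the change in the other line and do not show that the lines respond differently. They are PHOSPHO1, SLIT3, BDKRB2, GPR39, CLDN2 and LGALS7 (low in NCI-H460), and LINC01035, AC009119.1, AC109466.1, PLCB1, AL583722.1, AC011511.4, CDH13, EPHA5 and GKN2 (low in A549).

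With median-of-ratios scaling all 50 of these differences between lines had the same sign and 42 were still called. The other 8 were HES2 (0.91, adjusted p = 0.0654), CCNG1 (0.24, 0.315), TNFRSF10A (0.32, 0.0967), TNFRSF10B (0.27, 0.202), CCN2 (0.69, 0.119) and IFIT3 (0.40, 0.146) with candidate 42 ASO3, ACSS2 (0.88, 0.0663) with ASO5 and CENPA (-0.56, 0.0817) with candidate 240 ASO3. With each library of the compared groups left out in turn, all 50 also had the same sign, and 10 were called every time. Of these, FAS and OAS1 with candidate 42 ASO3, RAB3B with ASO5 and COL18A1 for the mean response to candidate 42 were tested in both lines. The others were PHOSPHO1, SLIT3, LINC01035 and AC009119.1 with candidate 42 ASO3, and CDH13 and EPHA5 for the mean response.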

How the results depend on the processing

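The fits without A549 replicate 3 and without the NCI-H460 candidate 42 ASO3 libraries were chosen after the results were seen, and the other alternatives before. No called fold change of a named gene changed sign, while AC107959.3, not called, did so without single libraries with candidate 240 ASO1 in A549 (-0.48 to 0.01) and candidate 42 ASO5 in NCI-H460 (-0.39 to 0.38). With a pseudocount of 0.1 and with median-of-ratios scaling, every total of genes and of lists was within 1.5 times the reported one. That scaling moved the split into higher and lower genes, from 1819 and 4513 to 3229 and 3222 for candidate 42 ASO3 in NCI-H460, from 3814 and 774 to 2178 and 1990 between the candidate 42 ASOs there, and from 273 and 1331 to 482 and 815 between candidates there. For differences between lines it turned the balance over, from 122 and 66 to 77 and 105 for candidate 42 and from 2286 and 623 to 1166 and 1383 for its ASO3. The excess of the mean r between lines for pairs against the same candidate (0.06) ranged from 0.042 to 0.084 with single libraries left out. Where a count moved, the cause was not tested, except that single-library and compared-group fits hold fewer libraries.

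With a pseudocount of 1, limma called 1 gene with candidate 240 ASO1 in NCI-H460 and 4 differing between lines for candidate 240. At a mean of at least 5 TPM, lists called with both candidate 42 ASOs in NCI-H460 numbered 2. With no filter, 5 genes were called in A549 with candidate 240 ASO1, 133 with both candidate 42 ASOs and 4 with both candidate 240 ASOs, and 8 lists with both candidate 42 ASOs. In NCI-H460 that fit called 44 genes with candidate 240 ASO1, 373 with ASO3, 22 with both, 215 between these ASOs and 657 between candidates, and 56 differing between lines for candidate 240.

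With an estimated inter-gene correlation, camera called 0 lists with both ASOs of either candidate in either line. fry called 0 with both ASOs of candidate 240 in A549 and of either candidate in NCI-H460.

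In fits of the compared groups alone, A549 gave 762 genes with candidate 42 ASO3, 119 with ASO5, 665 with candidate 240 ASO3 and 1271 between the candidate 240 ASOs. NCI-H460 gave 4088 with candidate 42 ASO3, 1922 between the candidate 42 ASOs, 253 between the candidate 240 ASOs, 978 between candidates and 1 with both candidate 42 ASOs.

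With the replicate block, the A549 comparisons whose libraries the numbers pair gave 3696 genes with candidate 240 ASO3, 3152 between the candidate 42 ASOs and 4411 between the candidate 240 ASOs. The block changed no other call there, of a named gene or of a list called with both ASOs. Where the numbers fell short of the pairing rule, it gave 3112 genes with candidate 42 ASO3 in A549, 1533 with ASO5, 599 with both and 2799 between candidates. The correlations there were still 0.02 to 0.41 over the candidate 42 and control libraries and 0.06 to 0.48 between candidates. A replicate effect in these libraries is thus not excluded. Differences between lines, where the numbers pair the A549 libraries of candidate 240 and no NCI-H460 libraries, numbered 2650 and 22 for candidates 42 and 240. Of the A549 libraries not paired, 2 of 6 (ASO3), 3 of 6 (ASO5) and 10 of 12 (between candidates) correlated best with their own number. In NCI-H460 the counts were 6372, 50, 0 and 721 for candidate 42 ASO3 and ASO5 and candidate 240 ASO1 and ASO3, and 1613 between candidates, where 8 of 8 libraries correlated best with their own number.

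Without A549 replicate 3, 3070 genes were called with candidate 42 ASO3, 1742 with ASO5, 689 with both, 1 with candidate 240 ASO1, 3667 with ASO3, 3285 and 3728 between the ASOs of candidates 42 and 240, and 2845 between candidates. Lists called with both candidate 42 ASOs numbered 10, and 1493 and 14 genes differed between lines for candidates 42 and 240. Without the candidate 42 ASO3 libraries, NCI-H460 gave 387 genes with ASO5, 1963 with candidate 240 ASO3, 778 between the candidate 240 ASOs and 2 lists with both, and 2 genes differed between lines for candidate 240.

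With each library left out in turn, A549 counts were 832 to 1271 for candidate 42 ASO3, 207 to 449 for ASO5, 81 to 163 for both, 0 to 0 for candidate 240 ASO1 (267 genes had an unadjusted p under 0.05 with all libraries) and for both candidate 240 ASOs, and 1371 to 2199 for ASO3. They were 908 to 1247 and 1585 to 2200 between the ASOs of candidates 42 and 240, 805 to 1483 between candidates, and 4 to 8 and 0 to 4 lists with both ASOs. In NCI-H460 they were 3698 to 7475 for candidate 42 ASO3, 0 to 0 for ASO5 (70 with all libraries), 0 to 325 for both, 0 to 2 for candidate 240 ASO1 and for both candidate 240 ASOs, and 76 to 392 for ASO3. They were 1980 to 6253 and 52 to 179 between the ASOs, 464 to 4171 between candidates, and 2 to 5 and 1 to 3 lists with both ASOs. Between lines they were 13 to 823 for candidate 42 and 0 to 3 for candidate 240. The lowest counts came without NCI-H460 control replicate 2 for candidate 42 ASO3 and candidate 240 ASO3 in that line, and without control replicate 1 for differences between lines for candidate 42.

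For named genes, 265 of the repeats without single libraries ended a call, 5 added one and 1275 left the gene on its side of the threshold. A call ended for 7 with a pseudocount of 0.1, 5 with 1, 40 with no filter, 0 at 5 TPM, 9 with median-of-ratios scaling, 7 with the block, 42 with the compared groups alone, 3 without A549 replicate 3 and 0 without the NCI-H460 candidate 42 ASO3 libraries. The unknown depth leaves the precision of low values open, so changes of genes near 1 TPM rest on the spread between libraries alone.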

Other observations

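The tests of the genes lowered in both lines were chosen after the result was seen, and the bounds of these tests were revised 2 times, while the splits of the samples were planned.

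Genes lowered by the same ASO in both lines had long gene bodies, with median genomic spans of 103, 105 and 151 kb for candidate 42 ASO3, candidate 42 ASO5 and candidate 240 ASO3, against 10.2, 6.69 and 13.4 kb for genes raised in both and 20.8, 28.1 and 27.5 kb for genes called in neither (lowered against raised, p = 1e-05, 3e-05 and 1e-05; 1e-05 is the smallest that 100000 permutations can give). As a hypothesis, each ASO may cleave long unspliced transcripts that its own sequence pairs with: for candidate 42 ASO5 and candidate 240 ASO3 the tests were in line with it, with spans 15.7 and 11.3 times as long as those of raised genes, and an overlap between lines (95% intervals of the odds ratio 55.2 to 262 and 19.7 to 31.2) above that with any other ASO in either line (odds ratios of at most 4.87 and 5.50). For candidate 42 ASO3 the test leaves it open, since the overlap between lines (odds ratio 3.13, 95% interval 2.71 to 3.62) was below that of its A549 genes with candidate 240 ASO3 in NCI-H460 (5.50, 4.27 to 7.04), but above that of its NCI-H460 genes with any other ASO in A549 (2.38 at most, 2.09 to 2.71), so that its own sequence cannot be told apart from a response that ASOs share. Overlaps were also taken within 10 bins of genomic span. For candidate 42 ASO5 and candidate 240 ASO3 (odds ratios 54.3 and 13.7) they argue against a general lowering of long genes as the whole cause. For candidate 42 ASO3 the odds ratio of 1.95 does not decide this, since genes measured well in both lines are more easily called in both. Scaling is argued against by the 96.4% and 93.6% of the genes of candidate 42 ASO5 and candidate 240 ASO3 still called in both lines with median-of-ratios scaling. The 74.3% for candidate 42 ASO3 leaves scaling as a part. For the candidate 42 ASO5 genes in A549, ASO3 left 8.55% of the target against 45.0% with ASO5. It moved these genes by only 0.23 of the ASO5 change (95% interval over genes 0.06 to 0.40). This argues against loss of the target only under a bound looser than that for the other ASOs and set after the values were seen. The genes were also chosen by their fall with ASO5, which lowers the ratio, and the ASO5 change of the target itself did not pass (limma, adjusted p = 0.166). Loss of the target cannot be told apart in NCI-H460 (0.75, 0.60 to 1.14), where ASO5 left 95.5% of a low target and ASO3 moved 1999 long genes by a median of -0.69. Nor can it for candidate 42 ASO3 and candidate 240 ASO3, whose other ASO left more of the target (medians of -0.14 and 0.06 in A549).

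The candidate 42 ASO5 genes rest on NCI-H460 calls, 0 of which were made without any 1 of the 4 libraries compared. The intervals of the odds ratios and the permutation p-values of the spans treat genes as independent, which they are not, so they overstate the certainty. The ASO sequences, which would allow a direct search for pairing sites, were not used.

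In A549, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real and highest other counts were 1482 and 1 for candidate 42 ASO3 (1 split as large, the real one included), 563 and 0 for ASO5 (1 split), 0 and 0 for candidate 240 ASO1 (10 splits), 2036 and 0 for ASO3 (1 split), 1570 and 0 between the candidate 42 ASOs (1 split) and 2465 and 1 between the candidate 240 ASOs (1 split). Where the numbers pair libraries, the other splits parting all 3 pairs called at most 0 genes.

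For genes called with both candidate 42 ASOs in A549, 2 of 100 splits, the real one included, gave as many as the real 203. Splits that mix the libraries of an ASO with others widen the spread within groups, so this share does not test whether the ASOs share an effect. The highest other split gave 605 genes. It set the 3 ASO3 libraries as controls for mixed control and ASO5 libraries, which points to a structure of the samples that follows that ASO. The ASO3 libraries differed from control at 1482 genes and from ASO5 at 1570. The 605 genes therefore do not measure what a shared reference group alone would give. For lists called with both, 23 of 100 splits gave at least the real 5 (highest other 8), so chance is not excluded. For candidate 240 the real count was 0 genes, so all 100 of 100 splits gave as many and the splits test nothing (highest other 1784), and for the 1 list (89 of 100, highest other 14) chance is not excluded. The numbers pair these libraries, and of the 17 splits that part all of them, the real one included, the others gave at most 0 genes and 9 lists. The split with 1784 genes again had the 3 ASO3 libraries as controls. Between candidates in A549, 1 of 100 splits, the real one, gave as many genes as the real 1194 (highest other 569). The splits divide libraries and not ASOs, and each candidate has only 2 ASOs, so this cannot part a difference between candidates from one between single ASOs. In NCI-H460, 2 of 35 splits gave as many as the real 1604, and chance is not excluded. The highest other split (2922) set candidate 42 ASO3 and candidate 240 ASO3 against the other ASOs, again a structure that follows the ASOs.

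Further lists that passed with single ASOs, chosen here after their values were seen, are given with members called higher and lower and camera's adjusted p. In A549, candidate 42 ASO3 gave epithelial-mesenchymal transition (0 and 5 of 21, 0.00964), DNA repair (1 and 3 of 29, 0.0139) and G1/S genes (0 and 3 of 34, 0.016), and ASO5 gave hypoxia (4 and 0 of 28, 0.0172). Candidate 240 ASO3 gave autophagy (1 and 8 of 24, 0.0167) and DNA repair (1 and 5 of 29, 0.0266). With candidate 240 ASO1, integrated stress response genes (lower, 29 members, 6.75e-10) and heat shock genes (higher, 17 members, 3.75e-06) passed with 0 members called. In NCI-H460, candidate 42 ASO3 gave cytosolic ribosomal proteins (9 and 0 of 57, 1.8e-09; 39 and 0 with median-of-ratios scaling) and mitochondrially encoded genes (7 and 0 of 13, 0.00311). There, candidate 42 ASO5 gave p53 targets (3 and 0 of 29, 5.01e-05) and NF-kB genes (3 and 0 of 20, 3.66e-05), and candidate 240 ASO3 gave heat shock genes (2 and 0 of 17, 6.37e-05) and the unfolded protein response (0 and 4 of 21, 0.00224). With an estimated inter-gene correlation none of these 14 passed (adjusted p of 0.0935 to 0.666).

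Of the marker lists, lung and squamous lists in A549 and fibroblast and neuroendocrine lists in both lines had enough members. None of the lung, squamous and fibroblast lists passed with any ASO. Values of the neuroendocrine list (6 members in each line) are not given here. The lowest adjusted p was 0.221 for lung (7 members), 0.262 for squamous (6), 0.284 for fibroblast in A549 (5) and 0.292 for fibroblast in NCI-H460 (6), and leukocyte and endothelial lists were not tested.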
